A study of Homo sapiens with 12 samples.

How the data were processed

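HCT116 cells, a human colorectal cancer line, were sequenced with and without β-elemene, a plant sesquiterpene. The dose and the duration are not given in the sources used here. Total RNA libraries (6) and small RNA libraries (6) were made, with 3 control and 3 treated libraries of each kind. Groups and replicate numbers came from the sample titles. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

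Per the file headers, the authors' mRNA and lncRNA tables give a count, an FPKM and a TPM for each transcript in each library, and the miRNA table gives RPM. The submitters' processing notes name HISAT2, Cufflinks and the mouse build mm9, with no role or version. The transcript IDs are human Ensembl IDs or IDs that start with MSTRG. Of 7498 circles with 1 host gene that has a span in GRCh38, 99.1% lay inside that span, so the circle positions fit the human build GRCh38. The caller of the circles is not given in the sources used here.

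The deposited counts of the transcript tables are whole numbers. They behaved as estimated counts that the authors rounded up, since 759 counts of 1 stood beside a median of 0.273 estimated reads, taken from the deposited FPKM, among mRNA-table transcripts above 1000 counts elsewhere. Count divided by deposited FPKM was the same in all libraries for a given transcript (0.9995 to 1.0005 relative to control library 1, 1st to 99th percentile, over 7203 transcripts). The counts and the FPKM values therefore carried the same scaling between libraries. Whether both follow the raw depth or both were scaled to library size cannot be told from this ratio. The counts were tested as deposited. The listed TPM values of the deposited mRNA table summed to 269960 to 276645 per library. FPKM and TPM were not used further. The deposited circRNA counts are junction reads, with a smallest nonzero count of 2, and 52 circles stood on 2 rows that were summed, which gave 8136 circles. Host genes were named from the Ensembl gene IDs in the table, of which 3636 of 3641 matched a symbol. The deposited RPM values of the miRNA table were whole multiples of a step in each library, within a tolerance of 0.02 of a step, and the smallest listed value was 2 steps. The step implies 6716149 to 19543936 reads per library, used here as a guide to relative depth only. The authors' deposited tables also hold log2 fold changes with p-values and adjusted p-values, which are quoted only where the authors' deposited table is named.

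Count tables were tested with edgeR 4.0.16 (R 4.3.3), by its quasi-likelihood test with TMM scaling. Low transcripts were removed with filterByExpr at a minimum count of 10 and a minimum total of 15, and low circles at 2 and 6. The RPM values were tested with limma 3.58.1 (empirical Bayes with a trend) on log2(RPM + 1), for miRNAs at 1 RPM or more in at least 3 libraries. Fold changes of miRNAs are on that scale, which understates changes of low miRNAs. All tests were two-sided, with Benjamini-Hochberg adjustment over the tested features of a table and a threshold of 0.05 with no fold minimum. The smallest p that an exact permutation test of 3 against 3 libraries can give is 0.1.

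Lists of miRNAs (7), mRNAs (32) and lncRNAs (4) were fixed before the data were examined, as were the tests and the rule for named features. The miRNA lists were tested with limma's camera at a preset correlation of 0.01, for lists with at least 3 tested members. The mRNA and lncRNA lists were not run, because the tables give transcript IDs and no table that pairs transcripts with genes was used here. For the same reason the genes that were always to be named are not reported, and at most 2 transcript IDs per direction are printed for each table. The rule named the 5 miRNAs with the largest positive and the 5 with the largest negative change among those that passed, were at or above the median level and did not overlap between groups. It added miR-21-5p, miR-34a-5p and, from each miRNA list, up to 3 members that passed or, where none did, the 2 with the smallest raw p, given as values only. For the mRNA table it took the 8 largest changes in each direction by the same criteria, of which 2 each are printed. For circles it took the 3 with the smallest raw p, as values, because fewer than 3 passed. A fold against a group at 0 is a lower bound set by a floor of 3 counts over the group.

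The tests were checked on simulated data with 200 changed features. With the dispersions fitted to each table, none of 180 changed mRNA-table transcripts and none of 168 changed lncRNA-table transcripts was called at folds of 2, 4 and 8. A wider range was then simulated, chosen after that result was seen. For the mRNA table, none of 58 transcripts was called at 8-fold, 10 of 55 at 64-fold and 22 of 64 at 512-fold. For the lncRNA table the numbers were 17 of 61, 31 of 51 and 46 of 54, with 8 unchanged transcripts called. In these simulations the tests on the transcript tables therefore had little power for moderate changes at these dispersions. The real mRNA table had a call at an absolute log2 fold change of 0.93. Either the simulation understated the power for some transcripts or this call is false, which was not tested. With a dispersion of 0.05 in place of the fitted ones, 55 of 55 mRNA-table transcripts were called at 8-fold. For circles, 0 of 49 were called at 2-fold and 21 of 40 at 8-fold. For miRNAs, 27 of 68 were called at 1.5-fold and 51 of 61 at 2-fold, with 8 unchanged miRNAs called. A let-7 list moved down by 0.3 (log2) was called, and no list was called without a shift. That shift was larger than the median log2 fold change of the real let-7 list, -0.14. The estimated correlation between members of the real list was 0.27, and lists with correlated members were not simulated as a separate case. The check therefore cannot show how often camera calls such a list without a shift, or whether it finds a smaller shift.

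The alternatives were a replicate block, each library left out, no filter, stricter thresholds, DESeq2 1.42.0, RLE scaling and limma-voom for counts, and other pseudocounts and scalings for RPM. Some also changed the tested features: DESeq2, which brings its own scaling and filter, tested 48871 mRNA-table transcripts, and the fits without 1 library tested 54596 to 54750, against 50862. A likelihood ratio test, circles summed per host gene, a test of hsa-named miRNAs alone and rescaled list tests were added after the data were seen.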

Results

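Total RNA and small RNA from HCT116 cells were profiled to ask how β-elemene, a plant sesquiterpene, changed the transcriptome of these cells. Each kind of library had 3 controls and 3 treated samples. The mRNA table held 71836076 to 79491003 estimated counts per library over 102164 transcripts, the lncRNA table held 660593 to 833879 over 47304 transcripts, and the circRNA table held 15121 to 18388 junction reads over 8136 circles. The miRNA table listed 1352 miRNAs, of which 974 had an hsa name and 378 a provisional ID. The RPM step implied 13344564 to 14129919 reads in the control small RNA libraries, but 13885911, 6716149 and 19543936 in treated replicates 1, 2 and 3, so the treated libraries were of unequal precision.

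Among miRNAs, miR-210-3p, a hypoxia-induced miRNA, rose with β-elemene, while let-7i-5p, of the let-7 tumour suppressor family, and miR-196b-5p, encoded in a HOX cluster, fell. miR-210-3p went from 222.1 ± 12 to 322.7 ± 32.6 RPM (SD, n = 3 per group), a log2 fold change of 0.53 ± 0.10 (SE; limma adjusted p = 0.0318). let-7i-5p went from 16621 ± 1069 to 12742 ± 191 RPM (SD, n = 3 per group), a log2 fold change of -0.38 ± 0.08 (SE; limma adjusted p = 0.0318). miR-196b-5p went from 429.7 ± 59.6 to 297.2 ± 19.8 RPM (SD, n = 3 per group), a log2 fold change of -0.52 ± 0.11 (SE; limma adjusted p = 0.0318). At lower levels, miR-3201 rose from 10.3 ± 1.67 to 20.9 ± 1.41 RPM and miR-3182 fell from 9.18 ± 3.79 to 3.22 ± 0.84 RPM (SD, n = 3 per group), with limma adjusted p of 0.0131 and 0.0318. For each of these 5, all 3 treated libraries lay on one side of all 3 controls, as they do by chance for 10% of features with 3 against 3. The naming rule required this for all but miR-210-3p, and all 19 miRNAs that passed showed it. The separation is therefore no added support. miR-210-3p, let-7i-5p, miR-196b-5p and miR-3182 each passed in 1 of the 6 fits without 1 library and miR-3201 in 3, with limma adjusted p of up to 0.221, 0.186, 0.186, 0.23 and 0.148 over all alternatives.

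In all, 19 of 1210 tested miRNAs passed, 15 higher and 4 lower, with absolute log2 fold changes of 0.38 to 1.54. Named miRNAs made up 9 of them and provisional IDs 10. miR-31-3p, miR-148b-3p, miR-4506 and miR-4695-5p, which the naming rule did not select and which were named after their values were seen, also rose, by log2 fold changes of 0.58, 0.44, 1.54 and 1.37 (limma adjusted p of 0.0318, 0.041, 0.0318 and 0.0318). Without 1 library the first 3 passed in 1, 0 and 2 of 6 fits, and miR-4695-5p in 0 of the 3 fits in which it met the RPM minimum. The last 2 were near the floor: miR-4506 went from 1.10 ± 0.51 to 5.54 ± 3.39 RPM and miR-4695-5p from 0.67 ± 0.29 to 3.50 ± 1.69 RPM (SD, n = 3 per group). The controls of miR-4695-5p, at 0.71, 0.94 and 0.37 RPM, were all under the minimum of 1 RPM, so it was tested only through the treated libraries. Both were highest in treated replicate 2, the shallowest library, at 9.23 and 5.21 RPM. Among the provisional IDs, 17_24677 rose from 9.26 ± 1.49 to 20.2 ± 3.56 RPM and 17_25004 fell from 34.9 ± 3.26 to 16.9 ± 2.52 RPM (SD, n = 3 per group), with limma adjusted p of 0.0131 and 0.0097. The rule also took 1_2166, 19_28742 and 7_54051, with log2 fold changes of 1.0, 0.75 and 0.84. miR-21-5p, an abundant oncogenic miRNA, was 43688 ± 2903 RPM in controls and 47657 ± 4586 RPM in treated cells (SD, n = 3 per group; limma adjusted p = 0.54), and did not pass.

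**Figure D1:**
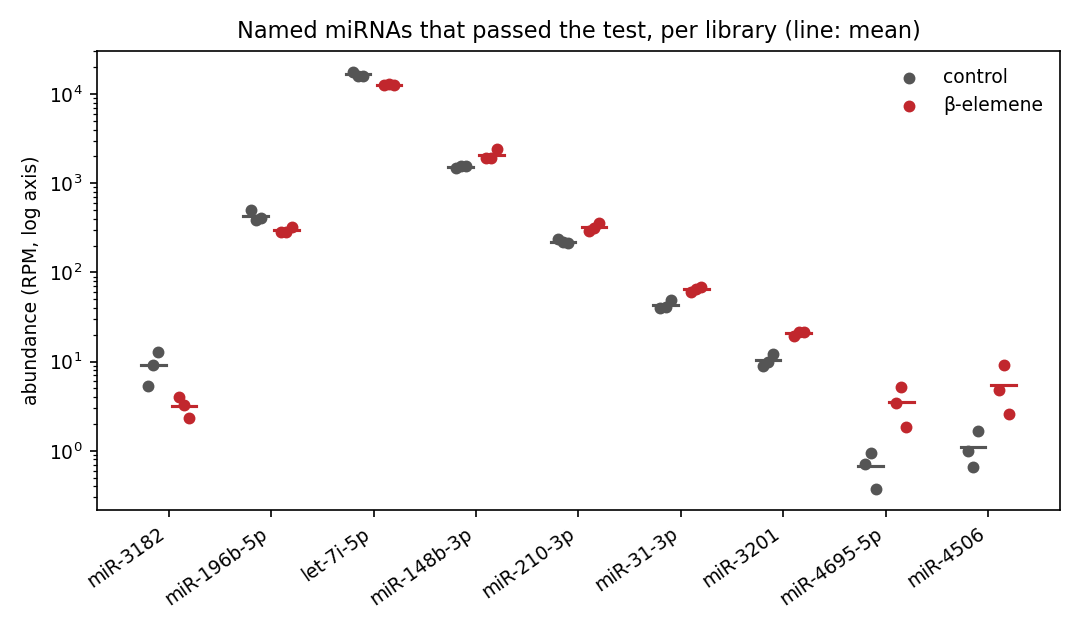
RPM on a log axis of the 9 hsa-named miRNAs that passed the test, with 1 point per library and a line at each group mean. The 3 treated libraries lie apart from the 3 controls for each miRNA, with let-7i-5p the most abundant.

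Of the 9 fixed members of the let-7 family, all of them tested, let-7i-5p fell and 8 did not pass over all tested miRNAs. Adjusted over the list alone, let-7i-5p and let-7a-5p passed. The other members given here were chosen after their values were seen. let-7a-5p had a log2 fold change of -0.28 ± 0.09 and let-7c-5p of -0.30 ± 0.11 (SE), whereas let-7f-5p was at 0.07 ± 0.08 and miR-98-5p at 0.18 ± 0.08 (SE). The list ranked lower than other miRNAs (camera adjusted p = 0.0013, median log2 fold change -0.14), with 7 members below 0 and 2 above, or 8 and 1 with libraries rescaled to a common median. The call was lost with an estimated correlation (adjusted p = 0.66), with fry, which asks whether the members themselves moved in one direction (adjusted p = 0.076), with quantile normalization (adjusted p = 0.068) and without treated replicate 1 (adjusted p = 0.063). Over all alternatives the adjusted p ran from 1.1e-04 to 0.66. The mixed test of fry, which asks whether members moved in either direction and was chosen after its values were seen, gave an adjusted p of 1.3e-04 for let-7. It gave 1.1e-04 for the p53-linked list, 1.2e-04 for the oncogenic or stress-linked list, 0.0036 for the tumour-suppressor-linked list and 0.0069 for the miR-200 list. The miR-17/92 list, at 0.63, and the list of other cell types, at 0.85, did not pass it. The mixed test does not compare a list with other miRNAs and was run on the values as deposited only. Of all 1210 tested miRNAs, 193 had an unadjusted limma p under 0.05 and 65.2% lay above 0. Passing the mixed test therefore does not set a list apart from miRNAs at large.

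**Figure D2:**
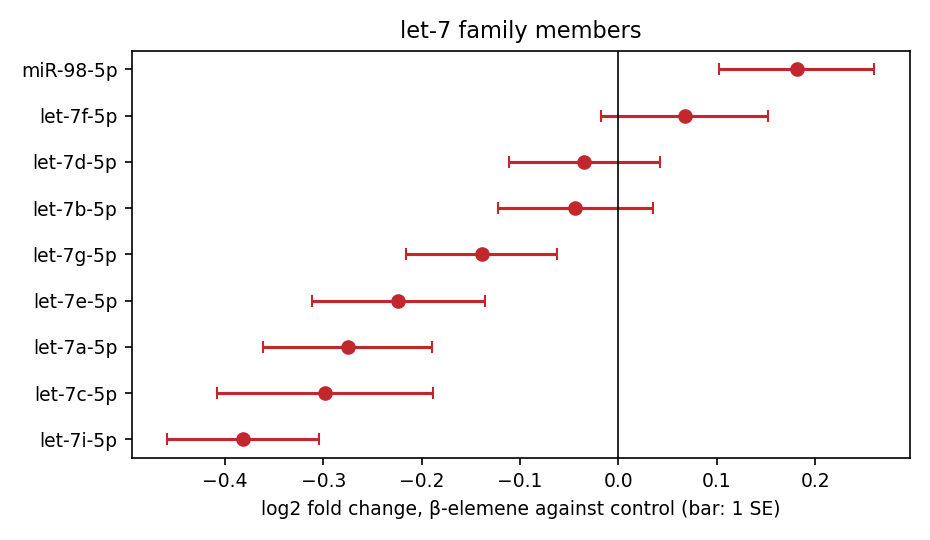
Log2 fold change of treated against control for the 9 let-7 family members (x axis), with bars of 1 SE. let-7i-5p lies lowest at -0.38 and miR-98-5p highest at 0.18; with libraries rescaled to a common median, 8 members in place of 7 lay below 0.

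No other list passed camera. In the oncogenic or stress-linked list, miR-210-3p rose and 14 of 15 tested members did not pass; adjusted over the list alone, 3 were higher (camera adjusted p = 0.31). In the p53-linked list none of 8 tested members passed over all miRNAs, and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.93). miR-34a-5p, a direct p53 target, was 206.3 ± 21.3 RPM in controls and 156.5 ± 12.3 RPM in treated cells (SD, n = 3 per group; limma adjusted p = 0.098), and miR-192-5p had a log2 fold change of 0.32 ± 0.11 (SE; limma adjusted p = 0.17). The list fixed as the miR-200 family, which restrains mesenchymal transition, also held miR-205-5p, which is not a member of that family. None of its 6 miRNAs passed (camera adjusted p = 0.93), and adjusted over the list alone miR-141-3p was higher and miR-205-5p lower. The 5 family members had log2 fold changes of 0.31 for miR-141-3p, 0.18 for miR-200a-3p, 0.05 for miR-200b-3p, 0.02 for miR-429 and -0.06 for miR-200c-3p. miR-205-5p, at 3.46 RPM in controls and 1.75 RPM in treated cells, had -0.72, which set the sign of the list's mean of -0.04 against its median of 0.03. In the tumour-suppressor-linked list none of 13 tested members passed and adjusted over the list alone 1 was lower (camera adjusted p = 0.31), with -0.40 for miR-375-3p and 0.17 for miR-16-5p. Its members lay above 0 in 12 cases and below in 1, or 10 and 3 with libraries rescaled to a common median or quantile normalized. Of all tested miRNAs, 65.2% lay above 0 as deposited. In the miR-17/92 and paralogous clusters none of 11 tested members passed by either adjustment (camera adjusted p = 0.77). The median was 0.03 while camera ranked the list lower, with 0.31 for miR-18a-5p and -0.13 for miR-93-5p. Of the list of miRNAs of other cell types, 3 were tested and none passed by either adjustment (camera adjusted p = 0.77), with 0.30 for miR-150-5p and -0.11 for miR-142-5p, of leukocytes, and -0.30 for miR-122-5p, of liver. No muscle or red cell miRNA of the list was tested.

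The miRNA count changed with the scaling and with the library left out. It was 9 (3 higher, 6 lower) with libraries rescaled to a common median and 1 (lower) with quantile normalization. It was 0 without control replicate 2 or without treated replicate 2, the shallowest library. It was 2 without control replicate 1 and 5 without treated replicate 1, but 13 without control replicate 3 and 17 without treated replicate 3. Fits without 1 library have less power, which was not told apart from dependence on a given library. The median log2 fold change over all tested miRNAs was 0.09 as deposited. The authors' deposited table calls 24 miRNAs higher and 12 lower, of which 2 have an adjusted p under 0.05 in that table. The smallest absolute log2 fold change among these calls is 1.01, and 33 miRNAs of the same table have an adjusted p under 0.05.

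Circular RNAs, measured by reads across the back-splice junction, showed no change that passed. Of 1777 tested circles 0 passed edgeR's quasi-likelihood test and 50 had an unadjusted p under 0.05; DESeq2 called 0 and limma-voom 1. The 3 circles with the smallest raw p had hosts in GAPVD1, RANBP9 and TOP2A. The GAPVD1 circle (chromosome 9, 125337018 to 125337591) had 0, 3 and 0 junction reads in controls and 13, 11 and 9 in treated libraries. The RANBP9 circle (chromosome 6, 13632370 to 13644729) had 8, 3 and 6 in controls and 17, 19 and 14 in treated libraries. The circle of TOP2A, a DNA topoisomerase of dividing cells (chromosome 17, 40406384 to 40406942) had 4 in each control and 12, 16 and 9 in treated libraries. All 3 had an edgeR adjusted p of 0.99. Summed per host gene, 0 of 1438 genes passed and 42 had an unadjusted p under 0.05. The authors' deposited table calls 1 circle higher, with its host in MAP7 (chromosome 6, 136359820 to 136421799), which had 52 junction reads in treated replicate 3 and 0 in the other 5 libraries, a number taken from the same table.

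Of 50862 tested transcripts in the mRNA table, 19 passed edgeR's quasi-likelihood test, 8 higher and 11 lower. MSTRG.541.5 had 12812, 13838 and 15364 counts in the treated libraries and 0 in each control, at least 14568-fold higher by the floor of 3 counts over the group (edgeR adjusted p = 0.0216). ENST00000325234 had 11592, 8762 and 10115 counts in treated libraries and 0 in controls, at least 10589-fold higher (edgeR adjusted p = 0.031). ENST00000403525 had 17994, 17779 and 14830 counts in controls and 0 in treated libraries, at least 16196-fold lower (edgeR adjusted p = 0.0216), and MSTRG.26441.8 had 5535, 5325 and 5536 counts in controls and 0 in treated libraries, at least 5250-fold lower (edgeR adjusted p = 0.031). These transcripts are not named here, since the IDs could not be paired with genes. The smallest absolute log2 fold change among the 19 was 0.93, and 5 of them were at 0 in one whole group. The transcripts printed above are all among these 5. The call with the smallest adjusted p, chosen after its values were seen, had counts in both groups. It had 440, 441 and 503 in controls and 16811, 16821 and 18324 in treated libraries (edgeR adjusted p = 0.0035).

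The spread between replicates was wide, with a common dispersion of 0.97, and log2 CPM correlated across transcripts at 0.82 within groups and at 0.81 to 0.82 between groups. The count was 1605 with DESeq2, 34 with limma-voom and 0 to 8 with 1 library left out. Of the 19 transcripts, DESeq2 called all 19 and limma-voom 14, but any fit with 1 library left out called at most 2. The authors' deposited table calls 534 transcripts, of which 343 were at 0 in all 3 libraries of one group.

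**Figure D3:**
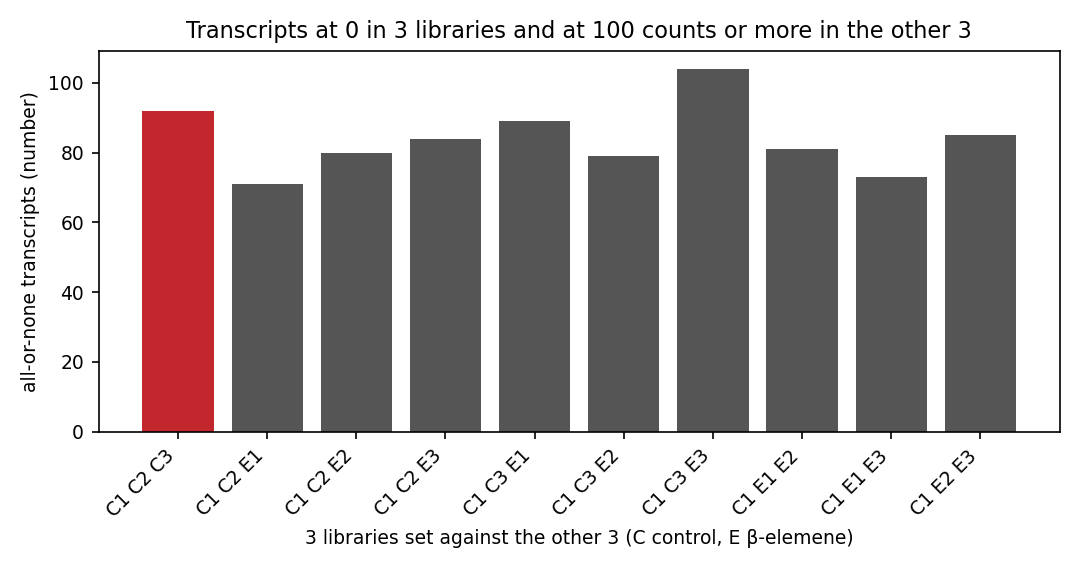
Number of mRNA-table transcripts at 0 in 3 libraries and at 100 counts or more in each of the other 3 (y axis), for the 10 ways to set 3 of the 6 libraries against 3 (x axis). Control against treated (red) gave 92, and the other 9 ways gave 71 to 104.

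Of 6469 tested transcripts in the lncRNA table, 1 passed. ENST00000664247, chosen after its values were seen because it was the only call, had 185, 199 and 130 counts in treated libraries and 1 in each control (edgeR adjusted p = 0.0098). The count was 57 with DESeq2 and 0 with limma-voom, and 0 or 1 with 1 library left out, and ENST00000664247 itself passed in 1 of those 6 fits, the one without treated replicate 3. The authors' deposited table calls 24 transcripts higher and 15 lower, of which 31 were at 0 in all 3 libraries of one group.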

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

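The alternatives were set before the data were examined, except the likelihood ratio test, the sums per host gene, the test of hsa-named miRNAs alone and the rescaled list tests, which were chosen after seeing the data. Of the 29 named features 15 passed, and in 185 refits these kept the call in 94 and lost it in 91. Of all 361 refits, 360 kept the direction. Many could not have turned, since the block and the filter leave the fold change of a miRNA as it was, and features with groups apart keep their sign with 1 library left out. The exception was miR-122-5p, which did not pass. The count of mRNA-table transcripts, 19, was 9 with no filter, 1605 with DESeq2, 34 with limma-voom, 515 with the likelihood ratio test, 1 at an adjusted p under 0.01, and 0 to 8 with 1 library left out. The lncRNA count, 1, was 57 with DESeq2, 0 with limma-voom, 40 with the likelihood ratio test and 0 to 1 with 1 library left out. The circRNA count, 0, was 3 with no filter, 1 with limma-voom and 0 to 2 with 1 library left out. The miRNA count, 19, was 9 with median rescaling, 1 with quantile normalization, 10 for hsa-named miRNAs alone, 6 at an absolute log2 fold change of at least 1, 1 at an adjusted p under 0.01, and 0 to 17 with 1 library left out. The count of shifted miRNA lists, 1, was 0 with an estimated correlation, 0 with fry, 0 with quantile normalization and 0 to 1 with 1 library left out. The cause of these moves was not tested. Replicate numbers 1 to 3 were shared between groups. Deviations of same-numbered libraries correlated at -0.01 to 0.00 in the mRNA table, 0.01 to 0.04 in the lncRNA table, -0.07 to 0.01 for circles and -0.15 to 0.01 for miRNAs. No clear pairing by number was seen, but 3 pairs per table cannot exclude one, and the main tests took the libraries as unpaired. With the replicate block, 0 mRNA-table transcripts, 0 lncRNA-table transcripts, 1 circle, 19 miRNAs and 1 miRNA list passed. Libraries correlated best with their own number in 1, 2, 1 and 0 of 3 pairs of the mRNA, lncRNA, circRNA and miRNA tables. The mRNA and lncRNA lists were not run under any setting, as the transcripts could not be paired with genes. Depth limits low miRNAs most in treated replicate 2, where 1 RPM stands for 6.72 reads.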

Other observations

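The patterns, the circles and the hairpins were chosen after values had been seen, and the predictions were written before each test was run. The real count with DESeq2 had been seen before its splits were planned. The FAT1 circle (chromosome 4, 186706563 to 186709845) had 384.7 ± 39.5 junction reads in controls and 337.7 ± 39.0 in treated libraries, and the CYP24A1 circle (chromosome 20, 54157169 to 54171670), from the gene of vitamin D catabolism, 241.7 ± 15 and 200.0 ± 21.7 (SD, n = 3 per group). The circle of HIPK3 (chromosome 11, 33286413 to 33287511) had 99.7 ± 13.7 and 63.7 ± 14.4 (SD, n = 3 per group). These are raw junction reads. Scaled to depth, the log2 fold changes were -0.10 for FAT1, -0.19 for CYP24A1 and -0.58 for HIPK3 (edgeR adjusted p = 0.99 for each). Other abundant circles lay on both sides of 0, with 0.10 for SPECC1 and -0.29 for LPAR3. Circles with a count numbered 2891 ± 89.1 in controls and 2635 ± 105 in treated libraries (SD, n = 3 per group; exact permutation p = 0.1, the smallest that 3 against 3 can give). Controls 1 to 3 had 2835, 2845 and 2994 circles from 17042, 16521 and 18388 junction reads, and treated libraries 2592, 2559 and 2755 from 15174, 15121 and 17013. The share of depth in this difference was not tested. Of the host genes on the mRNA lists, 0 passed, and 1, PRKDC, with 2, 0 and 4 junction reads in controls and 6, 10 and 9 in treated libraries, had an unadjusted p under 0.05. Some abundant circles switched between libraries of one group. The circle listed under HLA-B (chromosome 6, 31271073 to 31355592) had 0, 0 and 602 junction reads in controls and 549, 513 and 568 in treated libraries. The circle listed under IFITM2 (chromosome 11, 309013 to 314356) had 173, 0 and 134 in controls and 0, 133 and 0 in treated libraries. Whether these junction reads came from circles of the listed genes or from reads placed at the wrong position was not tested.

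Of the mRNA-table transcripts, 92 were at 0 in all libraries of one group and at 100 counts or more in each library of the other. Transcript assignment that varies between replicates is a candidate explanation: splits of the libraries that mix the groups gave up to 104 such transcripts, and the real split gave 0.88 times that. Pairs of libraries also differed in this way, with 1126 to 1176 transcripts at 0 in one and at 1000 counts or more in the other within groups, and 1147 to 1234 between groups. Whether counts moved between transcripts of one assembled locus was left undecided. Over 34 loci the summed count had a median absolute log2 change of 0.45, under the bound of 1 written beforehand, but the loss of the switching transcripts with nothing moved would give 0.53, as the other transcripts held a median of 81.9% of the locus. A change of isoform use by β-elemene at some loci stays open and was not tested.

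miRNAs with provisional IDs had a median log2 fold change 0.05 above that of named miRNAs. Lower abundance was argued against by a matched comparison: against the 10 named miRNAs closest in level the difference stayed at 0.047 (permutation p = 0.0044 across miRNAs, which are not independent replicates). Sequencing depth was left undecided: the difference was -0.018 in treated replicate 2, the shallowest library, and 0.114 in treated replicate 3, the deepest, but 0.052 in treated replicate 1, whose depth lay within the range of the controls. The bound written beforehand had asked only for 1 of the 2 shallower libraries at 0 or below. Of the 10 splits of the libraries, 2 gave a difference as large, and the highest other split gave an absolute difference of 0.109.

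Across 192 hairpins, Spearman's rho of the log2 fold changes of the 5p and 3p arm was -4.07e-05 (permutation p = 0.9998) and Pearson's r 0.016 (permutation p = 0.83), across miRNAs, which are not independent replicates. The arms had the same sign in 121 hairpins. As 65.2% of all tested miRNAs lay above 0, arms without any link would also share a sign in part of the hairpins. Whether that accounts for all 121 was not tested. The bound written beforehand counted a correlation of 0 or below against a change of the whole hairpin. After the result was seen this was left undecided, because the value lay within its permutation spread. Both arms had an unadjusted p under 0.05 in 4 hairpins. Of all 1210 tested miRNAs 193 had such a p, so arms without any link would also give some such hairpins. How many was not computed, and the 4 are given as values only. The direction was the same in miR-301a (0.53 for 5p and 0.50 for 3p), miR-148b (0.33 and 0.44) and miR-212 (0.37 and 0.51). It was opposite in miR-34a (-0.39 and 0.53), whose 3p arm was low, at 4.31 RPM in controls and 6.78 RPM in treated libraries.

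The 10 splits of 6 libraries cannot give a share under 0.05. The real split gave 19 changed miRNAs and the highest other split 0, with 1 split as large. It gave 19 changed mRNA-table transcripts against 13 in the highest other split (1 as large), and with DESeq2 1605 against 917 (1 as large). It gave 1 lncRNA-table transcript against 3 (5 as large), 0 circles against 1 (10 as large) and 1 miRNA list against 5 (5 as large).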
